A study of Daphnia magna with 12 samples.

How the data were processed

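RNA from whole Daphnia magna was compared on 12 two-colour arrays after 21 days in culture medium alone or with PFECHS at 0.06, 0.6 or 6 mg/L. Per the labels, animals were kept at 20 °C with 16 h light and 8 h dark. The series' design text states 3 biological replicates per group, and the number of animals in a replicate is not given in the sources used here. Per the labels, each sample was labelled with Cy5 and hybridised against a reference of pooled controls in Cy3 on every array, with no dye swap, so a dye effect is shared by all groups. Per the labels, control replicate 3 was an outlier and was left out by the submitters, and it was left out of the comparisons here as well.

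Per the file headers, the arrays were read with Agilent Feature Extraction 10.1.1.1, which gave for each spot a mean pixel intensity and a median local background intensity in each channel. The same deposited files hold processed intensity values, which the scanner software had background-subtracted and dye-normalized, and a log10 ratio of red over green, per the file headers. That log10 ratio was within 0.001 of the value computed from the processed signals for 86.72% of spots and was not used. The deposited files also hold flags of 0 or 1 for outlier, saturated and well above background spots. The authors' deposited table gives, per probe, a log2 fold change, a p-value and an adjusted p-value for 6 comparisons. limma is named in the submitters' processing notes, and its version and the normalization behind that table are not given in the sources used here.

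Values were computed from the scanner files with R 4.3.3 and limma 3.58.1. Background was corrected with normexp (offset 50) on mean signals and median backgrounds over all 15744 spots. The 536 control spots were then left out, with weight 0 in the loess normalization within each array, and spots marked as outliers by the scanner software were removed. Between 0.125% and 0.993% of spots per array were so marked. The spots of each probe were averaged as log2 ratios of Cy5 over Cy3. The tests ran on the 7370 Daphnia probes, each 60 bases long, and 468 probes for Arabidopsis genes were left out. After removal of marked spots 72 values of a probe on an array were missing, and 7368 probes could be compared with the controls. The median Cy5 intensity was 183.9 to 290.4 per array, over a background of 75.5 to 80.0, and no Daphnia probe was saturated in Cy5. The number of arrays limits the precision. Probes not well above background in a group were few among those named, and the number of arrays above background is given with them.

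A limma linear model with 4 groups was fitted to 11 arrays, with 7 residual degrees of freedom, and p was adjusted with Benjamini-Hochberg at 0.05 over the Daphnia probes. The comparisons were each dose against control, each pair of doses, and a slope over the 4 ascending dose ranks. Arrays lay on 2 slides, each with its own scan time. Slide 1 held control replicates 1 and 2, replicates 1 and 2 at 0.06 mg/L and replicate 1 at 0.6 and 6 mg/L, and slide 2 held the other 6 arrays. As a term in the fit, slide passed for 0 probes in limma and had an unadjusted p under 0.05 for 393. The model was tested on simulated arrays with independent normal noise and 200 changed probes among 7370. Against control the model called 73.1%, 76.1% and 76.1% of probes changed 1.5-fold at 0.06, 0.6 and 6 mg/L, and 91.0%, 91.0% and 100% of those changed 2-fold. That noise had the same spread in all groups and no correlation between probes, so these shares are not the recovery on the real arrays. There 95, 61 and 23 probes were over 2-fold from control at 0.06, 0.6 and 6 mg/L, and 0 passed. To see what shared arrays and the choice of probes do alone, lists of 26 and 44 probes were taken by smallest p from 100 simulated sets of arrays with no dose effect, with independent normal noise alone or with the fitted slide differences added. Passing probes were counted on these, and on 100 more sets whose noise was mixed at random from the residuals of the model with slide, which keeps the correlation between probes (7313 probes without missing values).

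All 7370 Daphnia probes are described as unknown in the files, and 0 were found in the reference gene table, so no probe is given a gene name. For each dose the 2 probes with the largest rise and the 2 with the largest fall in log2 fold change are named by identifier, the rule set for files without gene names. The 19 gene lists, for yolk, cuticle and chitin, ecdysteroid and juvenile hormone, globin, digestive proteases, carbohydrate digestion, lipid metabolism, detoxification, antioxidant and metal response, chaperones, ribosome, oxidative phosphorylation, proteasome and ubiquitin, muscle, germline and embryo, cell cycle, immunity, eye and nerve, and algal food, held 0 Daphnia probes each, so neither a list nor the alternative list tests could be run. Probes were grouped into families when they shared an exact stretch of 30 bases. Family differences between controls and exposed arrays were tested with an exact permutation of the family medians per array.

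The alternatives were control replicate 3 included, with and without array quality weights or slide as a block, slide as a block, each slide alone, the replicate number as a block, no background correction, the scanner's processed signals, median centring, loess followed by Aquantile, the Cy5 channel alone, the authors' deposited table, a filter on dim probes that kept 6047, a trended and robust variance model, only the 2 groups compared, 2 other thresholds, and each array left out. Edwards background correction, 1 probe per sequence family (6404 probes), the Arabidopsis probes kept and the outlier spots kept were added after the data were seen.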

Results

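Gene expression was measured in whole Daphnia magna, a freshwater crustacean used in toxicity testing, after a 21-day exposure to perfluoroethylcyclohexanesulfonate (PFECHS), a cyclic perfluorinated sulfonate. Each of 12 two-colour arrays carried 1 sample in the Cy5 channel and a reference of pooled control RNA in the Cy3 channel. There were 3 arrays for culture medium alone and 3 arrays at each of 0.06, 0.6 and 6 mg/L. Control replicate 3 was set aside, since its label calls it an outlier that the submitters did not use, so 2 control arrays entered the comparisons. The array held 7370 probes for Daphnia, each 60 bases long and each described only as unknown, so that probes are given here by identifier and sequence. The identifiers fall into 2255 AF probes, 247 AM probes and 4868 UN probes, and the meaning of these letters is not given in the sources used here. Between 68.4% and 85.9% of the Daphnia probes were well above background in the Cy5 channel, depending on the array. On all 12 arrays this held for 90.6% of the AF probes, 39.3% of the AM probes and 56.2% of the UN probes. The number of arrays, with 2 or 3 per group, limits the precision of every value. Values are log2 ratios of sample to reference, and each difference is tested with limma and Benjamini-Hochberg adjustment over the Daphnia probes.

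The first comparison asked which transcripts differed from control at 6 mg/L. Probe EA_Dma_UN_103916 (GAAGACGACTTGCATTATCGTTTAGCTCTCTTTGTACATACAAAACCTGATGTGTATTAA) had a log2 ratio of -4.91 ± 0.69 (SD, n = 3) at 6 mg/L and -1.10 ± 1.23 (SD, n = 2) in the controls. The log2 fold change was -3.81 (SE 0.80, 95% confidence interval -5.59 to -2.03, limma adjusted p = 0.252), and all 3 exposed arrays lay below both controls. Probe EA_Dma_UN_102511 (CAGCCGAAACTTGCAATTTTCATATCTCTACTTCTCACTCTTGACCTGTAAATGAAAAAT) had the next lowest value, a log2 fold change of -2.41 (SE 1.17, adjusted p = 0.487). On the other side, EA_Dma_UN_103060 (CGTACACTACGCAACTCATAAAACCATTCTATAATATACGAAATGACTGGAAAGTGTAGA) stood at 3.94 ± 0.25 (SD, n = 3) in the exposed arrays and 0.06 ± 1.93 (SD, n = 2) in the controls, a log2 fold change of 3.88 (SE 1.5, adjusted p = 0.360). EA_Dma_UN_106812 (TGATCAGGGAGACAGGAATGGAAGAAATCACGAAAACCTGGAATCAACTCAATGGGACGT) followed with 3.61 (SE 1.38, adjusted p = 0.355). Both of these probes were well above background on 1 of the 2 control arrays and on all 3 exposed arrays. All 3 exposed arrays lay above both controls for each of them. None of the 4 probes passed the adjusted threshold. EA_Dma_UN_103916 passed it with control replicate 3 included under array quality weights (-4.24), where 6 mg/L replicate 1 had the highest weight (2.46). The probe stood at -5.57 within slide 2 and at -4.68 without control replicate 2, each with 1 control array. At an unadjusted p under 0.05 with a 1.5-fold change, EA_Dma_UN_103916 passed along with EA_Dma_UN_103060 and EA_Dma_UN_106812. The values of all 4 moved with the control arrays. Without control replicate 1 or 2, EA_Dma_UN_103060 stood at 5.24 or 2.51, EA_Dma_UN_106812 at 4.67 or 2.56, EA_Dma_UN_102511 at -1.49 or -3.34, and EA_Dma_UN_103916 at -2.94 or -4.68. The scanner's processed signals gave 6.69 for EA_Dma_UN_103060 and 6.62 for EA_Dma_UN_106812, and EA_Dma_UN_102511 was at -4.71 within slide 2. On 6 mg/L replicate 1 the background model left a Cy5 median of 193.8 on the Arabidopsis control probes, against 13.99 to 19.79 on the other arrays, while its plainly subtracted median was 7.82. With Edwards background correction, chosen after this was seen, or with no background correction, 0 probes passed at this dose as well.

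In total, 0 of 7368 probes passed at 6 mg/L, where the smallest adjusted p was 0.170. At an unadjusted p under 0.05, limma gave 824 probes, 258 with higher and 566 with lower values, where 368.4 would be reached by chance. A large part of the lower probes belonged to 1 group of near-identical sequences. Probes were grouped, after the data were examined, by sharing an exact stretch of 30 bases. The largest such family held 391 probes with 117 distinct sequences, and 160 of them carried the sequence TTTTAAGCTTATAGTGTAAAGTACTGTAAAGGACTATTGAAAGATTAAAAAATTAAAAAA. At 6 mg/L, 257 probes of this family were among the 566 lower ones (45.4%), with a median log2 fold change over the family of -0.33. Counted once per family, the 824 probes made 504 separate measurements. In the table deposited by the authors, likewise, 0 Daphnia probes passed an adjusted p of 0.05 at this dose, and 971 reached the unadjusted threshold. The count was also 0 with slide as a block, and 0 within slide 1. Within slide 2, where control replicate 3 is the only control, it was 441, of which 297 were in the largest family. Without control replicate 2 the count was 241, of which 168 were in that family, and with control replicate 3 included it was 5.

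The same question was asked at 0.6 mg/L. The highest values came from EA_Dma_AF_102134 (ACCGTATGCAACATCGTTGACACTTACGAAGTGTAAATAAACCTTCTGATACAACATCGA), with a log2 fold change of 4.26 (SE 2.39, adjusted p = 0.581), and EA_Dma_UN_107138 (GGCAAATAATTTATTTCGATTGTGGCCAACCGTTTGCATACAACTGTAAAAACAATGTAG), with 4.22 (SE 2.25, adjusted p = 0.565). Neither passed, and their 3 exposed arrays differed widely. EA_Dma_AF_102134 had log2 ratios of -1.56, 6.15 and 2.90 in replicates 1, 2 and 3, against -1.70 and -1.82 in the controls. EA_Dma_UN_107138 had -3.13, 3.87 and 2.04, against -3.23 and -3.36. On the left-out control replicate 3 these probes stood at 1.73 and 1.58, and that array lay on slide 2 with 0.6 mg/L replicates 2 and 3. For EA_Dma_AF_102134 and EA_Dma_UN_107138 the log2 fold change was 2.43 and 2.75 without 0.6 mg/L replicate 2, 6.29 and 6.25 without replicate 1, 1.36 and 1.56 with slide as a block, and 0.20 and 0.16 within slide 1. The lowest values were those of EA_Dma_UN_106596 (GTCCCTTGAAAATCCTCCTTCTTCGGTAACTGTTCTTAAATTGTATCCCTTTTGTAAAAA), at -1.29 (SE 1.25, adjusted p = 0.776), and EA_Dma_UN_106301 (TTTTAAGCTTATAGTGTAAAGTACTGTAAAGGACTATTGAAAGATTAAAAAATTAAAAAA), at -1.06 (SE 0.21, 95% confidence interval -1.52 to -0.59, adjusted p = 0.0796). The value of EA_Dma_UN_106596 turned to 1.81 within slide 2 and to 0.27 with control replicate 3 included and slide as a block. It was -0.51 without control replicate 1, -2.07 without control replicate 2 and -0.21 with slide as a block alone. EA_Dma_UN_106301 stood at -2.18 within slide 2 and at -1.39 without control replicate 2, each with 1 control array. This probe passed at an adjusted p under 0.1 and at an unadjusted p under 0.05 with a 1.5-fold change. It belongs to the largest sequence family and had 0.09 ± 0.26 (SD, n = 3) at 0.6 mg/L and 1.15 ± 0.47 (SD, n = 2) in the controls, with 3 of 3 exposed arrays below both controls. Its sequence is carried by 160 probes, of which it had the lowest value. Together these stood at 1.25 and 0.63 on control replicates 1 and 2 and at 0.07, 0.26 and -0.07 at 0.6 mg/L.

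At 0.6 mg/L, 0 of 7368 probes passed in limma, with 797 at an unadjusted p under 0.05, 223 higher and 574 lower. The largest sequence family supplied 271 of the 574 lower probes (47.2%), with a median log2 fold change of -0.36. In the authors' deposited table the count of passing Daphnia probes was 0, and 891 reached the unadjusted threshold. The count was 0 with slide as a block and 0 within slide 1, and it was 388 within slide 2 against control replicate 3. Without control replicate 2 it was 277, of which 217 were in the largest family, and with control replicate 3 included it was 1.

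At 0.06 mg/L the lowest values against control were carried by 2 of the 3 arrays. EA_Dma_UN_104730 (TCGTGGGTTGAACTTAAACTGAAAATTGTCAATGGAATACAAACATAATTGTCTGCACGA) had log2 ratios of -7.66, -7.15 and -1.75 in replicates 1, 2 and 3, against -0.28 and 0.11 in the controls, and its log2 fold change was -5.43 (SE 1.45, 95% confidence interval -8.68 to -2.18, adjusted p = 0.125). EA_Dma_UN_104131 (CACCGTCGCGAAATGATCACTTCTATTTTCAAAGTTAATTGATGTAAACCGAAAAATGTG) had -5.68, -5.36 and -0.27, against 0.17 and -0.03, with a log2 fold change of -3.84 (SE 1.32, adjusted p = 0.166). Its value turned to 0.61 within slide 2, where replicate 3 is the only array of this dose and EA_Dma_UN_104730 stood at -1.32. Without 0.06 mg/L replicate 3 both probes passed the threshold, at -7.32 and -5.59, as they did within slide 1, where that array is absent, and at an unadjusted p under 0.05 with a 1.5-fold change. EA_Dma_UN_104730 passed with control replicate 3 included and slide as a block too (-5.32). The highest values were those of EA_Dma_UN_103060, at 2.64 (SE 1.5, adjusted p = 0.397), and EA_Dma_AF_102134, at 2.54 (SE 2.39, adjusted p = 0.625). For EA_Dma_UN_103060 the value was 4.01 without control replicate 1, 1.28 without control replicate 2 and 5.25 with the scanner's processed signals. EA_Dma_AF_102134 was high on replicate 3 alone, at 5.59, while replicates 1 and 2 stood at -1.48 and -1.78, and its log2 fold change was 0.13 without replicate 3, 3.82 without replicate 2 and 1.09 with slide as a block.

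In limma 0 of 7368 probes passed at 0.06 mg/L, with a smallest adjusted p of 0.0577. The count at an unadjusted p under 0.05 was 1347, with 549 higher and 798 lower, of which 258 lower ones were in the largest sequence family. The AF probes had 20.1% and the UN probes 18.1% of their number at this level, and the AM probes 5.67%. The authors' deposited table likewise gave 0 passing Daphnia probes, and 1366 reached the unadjusted threshold, with a smallest adjusted p of 0.0528. The count of passing probes depended on the controls and on single arrays. It was 190 with control replicate 3 included, 254 with that array and slide as a block, 2 with slide as a block alone, 48 within slide 1 and 389 within slide 2. Leaving out control replicate 2 gave 316 and leaving out 0.06 mg/L replicate 3 gave 90, while leaving out control replicate 1, 0.06 mg/L replicate 2, 0.6 mg/L replicate 2 or 6 mg/L replicate 1 gave 2, 2, 2 and 3.

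**Figure D1:**
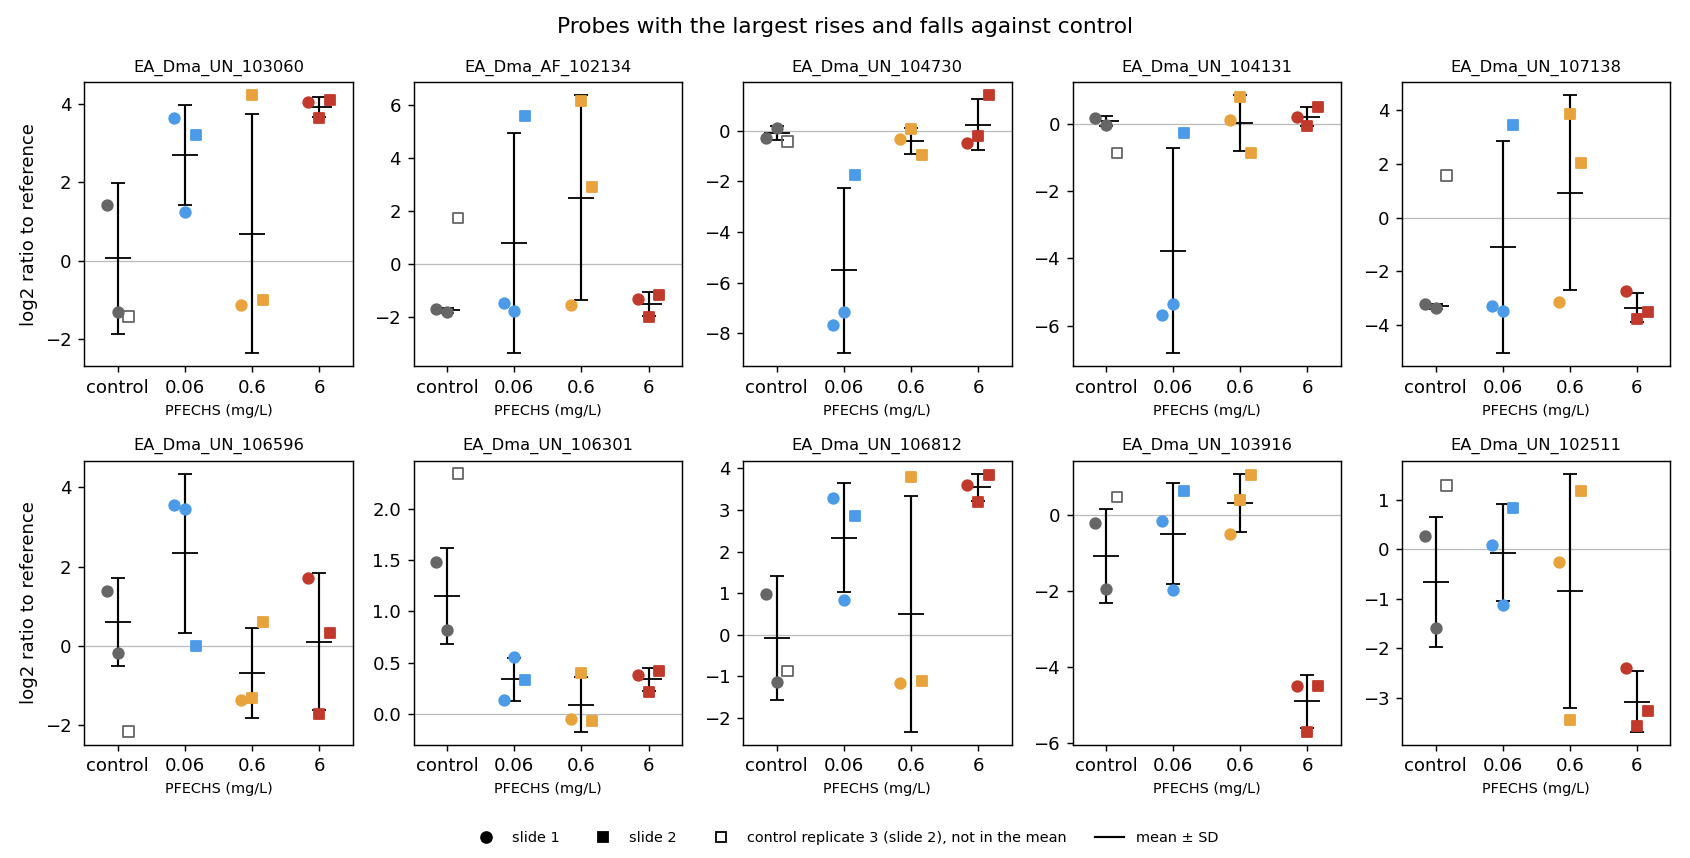
Log2 ratio of sample to reference (vertical axis) on each array, by PFECHS dose in mg/L (horizontal axis), for the 2 probes with the highest and the 2 with the lowest log2 fold change against control at each dose. Circles are arrays of slide 1 and squares of slide 2, the hollow square is control replicate 3, and bars are the mean ± SD without it. EA_Dma_UN_103916 lies between -5.71 and -4.50 at 6 mg/L, and EA_Dma_UN_104730 at -7.66 and -7.15 on 2 arrays at 0.06 mg/L and at -1.75 on the third.

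The doses were then compared with each other, without the control arrays in the contrast. Between 6 and 0.06 mg/L, 26 of 7370 probes passed, 11 higher and 15 lower at 6 mg/L, and none of these 26 was in the largest sequence family. The probes named for the comparisons between doses are the 2 largest rises and the 2 largest falls among those that passed, a choice made after their values were seen. EA_Dma_UN_103724 (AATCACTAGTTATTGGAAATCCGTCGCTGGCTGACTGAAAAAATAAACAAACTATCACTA) was 12.8-fold higher at 6 mg/L, with log2 ratios of 0.30 ± 0.79 (SD, n = 3) against -3.37 ± 0.90 (SD, n = 3) at 0.06 mg/L and -0.19 ± 0.59 (SD, n = 2) in the controls (limma adjusted p = 0.0360). EA_Dma_UN_103859 (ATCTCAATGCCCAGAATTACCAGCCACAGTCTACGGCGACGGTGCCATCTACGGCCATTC) passed with a log2 fold change of 2.00 (SE 0.33, adjusted p = 0.0416), again with the low value at 0.06 mg/L, -2.01 ± 0.46 (SD, n = 3). It was well above background on 2 of the 3 arrays there, so the size of its change is uncertain, and it was 2.48 in the authors' deposited table and 3.89 with the scanner's processed signals, where it did not pass. In the other direction, EA_Dma_UN_103916 fell by 4.40 on the log2 scale (SE 0.71, 95% confidence interval -6.0 to -2.81, adjusted p = 0.0416), here with the low value at 6 mg/L. EA_Dma_AF_101123 (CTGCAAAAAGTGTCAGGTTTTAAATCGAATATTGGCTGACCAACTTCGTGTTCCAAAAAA) fell by 1.19 on the log2 scale (SE 0.15, adjusted p = 0.0244), from 0.55 ± 0.29 (SD, n = 3) at 0.06 mg/L to -0.64 ± 0.15 (SD, n = 3) at 6 mg/L, on either side of the controls at -0.07 ± 0.15 (SD, n = 2).

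Of the 26 probes, 18 had a mean at 0.06 mg/L further from the control mean than the mean at 6 mg/L was, and 25 were well above background on all 12 arrays. With slide as a block 16 probes passed, 13 of them among the 26. Slide 1 held 1 array at 6 mg/L and slide 2 held 1 at 0.06 mg/L. The median log2 fold of the 26 in the direction of the call was 0.72 within slide 1 and 0.78 within slide 2, on the arrays that chose them. The authors' deposited table had 36 Daphnia probes past the threshold, of which 23 were among the 26. Leaving out single arrays moved the count and its split by direction. It was 6 (0 higher and 6 lower), 21 (3 and 18) and 84 (65 and 19) without 0.06 mg/L replicates 1, 2 and 3. It moved to 6 and 13 (0.6 mg/L replicates 1 and 3), and 1 (6 mg/L replicate 2 and likewise replicate 3). It was 1 with the scanner's processed signals and 0 with median centring in place of loess. EA_Dma_UN_103724 and EA_Dma_AF_101123 passed with slide as a block, and EA_Dma_UN_103859 (1.84) and EA_Dma_UN_103916 (-4.66) did not. Without background correction EA_Dma_UN_103724 (3.54), EA_Dma_UN_103859 (1.80) and EA_Dma_UN_103916 (-4.44) missed the threshold, and EA_Dma_UN_103724 and EA_Dma_UN_103916 missed it in the trended and robust model. All 4 missed it with the scanner's processed signals, with median centring, with only the 2 groups compared in the fit and within either slide. Their log2 fold changes over these settings were 3.08 to 4.36 for EA_Dma_UN_103724, 1.61 to 3.89 for EA_Dma_UN_103859, -5.74 to -3.43 for EA_Dma_UN_103916 and -1.60 to -1.09 for EA_Dma_AF_101123. EA_Dma_AF_101123 missed the threshold without 6 mg/L replicate 2 or 3 (log2 fold change -1.17 and -1.13). EA_Dma_UN_103724 missed it without replicate 1 or 2 at 0.06 mg/L (3.42 for each), 1 or 3 at 0.6 mg/L (3.68 for each), or 2 or 3 at 6 mg/L (3.58 and 3.35). EA_Dma_UN_103859 missed it without any one of replicates 1 and 2 at 0.06 mg/L (1.86 and 1.88), 1, 2 and 3 at 0.6 mg/L (2.00 for each) and 1, 2 and 3 at 6 mg/L (2.14, 1.91 and 1.97). EA_Dma_UN_103916 missed it without any one of replicate 1 at 0.06 mg/L (-4.24), replicates 1, 2 and 3 at 0.6 mg/L (-4.40 for each) and 1, 2 and 3 at 6 mg/L (-4.61, -4.00 and -4.60).

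Between 0.6 and 0.06 mg/L, 44 probes passed, 28 higher and 16 lower at 0.6 mg/L. EA_Dma_UN_103859 passed here as well, with a log2 fold change of 1.82 (SE 0.33, adjusted p = 0.0484), and did not pass in the authors' deposited table (2.23) or with the scanner's processed signals (3.63). EA_Dma_UN_105456 (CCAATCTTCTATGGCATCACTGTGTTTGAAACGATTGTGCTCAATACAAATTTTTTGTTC) was 3.05-fold higher (log2 fold change 1.61, SE 0.17, adjusted p = 0.0235), with 0.04 ± 0.23 (SD, n = 3) at 0.6 mg/L, -1.57 ± 0.09 (SD, n = 3) at 0.06 mg/L and -0.25 ± 0.44 (SD, n = 2) in the controls. EA_Dma_UN_107077 (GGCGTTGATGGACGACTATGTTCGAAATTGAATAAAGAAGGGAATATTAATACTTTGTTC) fell by 0.78 on the log2 scale (SE 0.12, adjusted p = 0.0408), from 0.84 ± 0.03 (SD, n = 3) at 0.06 mg/L to 0.06 ± 0.26 (SD, n = 3) at 0.6 mg/L. EA_Dma_AM_102500 (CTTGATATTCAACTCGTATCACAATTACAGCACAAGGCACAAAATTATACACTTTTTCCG), the only AM probe that passed in any of these comparisons, fell by 0.77 (SE 0.14, adjusted p = 0.0486), and did not pass in the authors' deposited table (-0.84, adjusted p = 0.0706). In 39 of the 44 probes the mean at 0.06 mg/L was further from the control mean than the mean at 0.6 mg/L was. Of the 44, 9 were also among the 26 that differed between 6 and 0.06 mg/L, where 2 independent lists would share 0.155. The comparisons share the 0.06 mg/L arrays, and part of this overlap may come from them. In simulated arrays with no dose effect, the 26 and 44 probes with the smallest p shared 5.09 on average and up to 11 over 100 simulations.

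With slide as a block 2 probes passed, of which 1 was among the 44. Slide 1 held 1 array at 0.6 mg/L and slide 2 held 1 at 0.06 mg/L. The median log2 fold of the 44 in the direction of the call was 0.68 within slide 1 and 0.50 within slide 2, on the arrays that chose them. The authors' deposited table had 17 Daphnia probes past the threshold, of which 14 were among the 44. The count fell to 0 without 0.06 mg/L replicate 1, 0.6 mg/L replicate 1 or 3, or 6 mg/L replicate 1, 2 or 3. It was 1 without 0.06 mg/L replicate 2, 162 (115 higher and 47 lower) without 0.06 mg/L replicate 3 and 99 (47 higher and 52 lower) without 0.6 mg/L replicate 2. Scanner processed signals and median centring each gave 0, no background correction gave 12 (9 higher and 3 lower), and the Cy5 channel alone gave 5 (4 higher and 1 lower). With Edwards background correction it was 18 (14 higher and 4 lower). Of the 4 named probes, EA_Dma_UN_105456 alone passed with slide as a block, without background correction, with Edwards correction, with Cy5 alone or with the replicate block. With the scanner's processed signals (1.59), median centring (1.5) and either slide alone (1.63 and 1.52) it missed the threshold too. The other 3 missed it in all of these settings, with log2 fold changes of 1.38 to 3.63 for EA_Dma_UN_103859, -0.93 to -0.74 for EA_Dma_UN_107077 and -0.89 to -0.68 for EA_Dma_AM_102500. With slide as a block these were 1.66, -0.78 and -0.69, and the replicate block left them as reported. EA_Dma_UN_105456 also missed the threshold without any one of replicates 1 and 2 at 0.06 mg/L (log2 fold change 1.57 and 1.59), 1 and 3 at 0.6 mg/L (1.63 and 1.49) and 1, 2 and 3 at 6 mg/L (1.61 for each). EA_Dma_UN_107077 missed it without the same arrays, with values of -0.80 and -0.77, -0.73 and -0.69, and -0.78 for each. EA_Dma_UN_103859 missed it without any of those or 0.6 mg/L replicate 2 (1.66 to 1.91), and EA_Dma_AM_102500 without any array but 0.06 mg/L replicate 3 (-0.81 to -0.71).

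**Figure D2:**
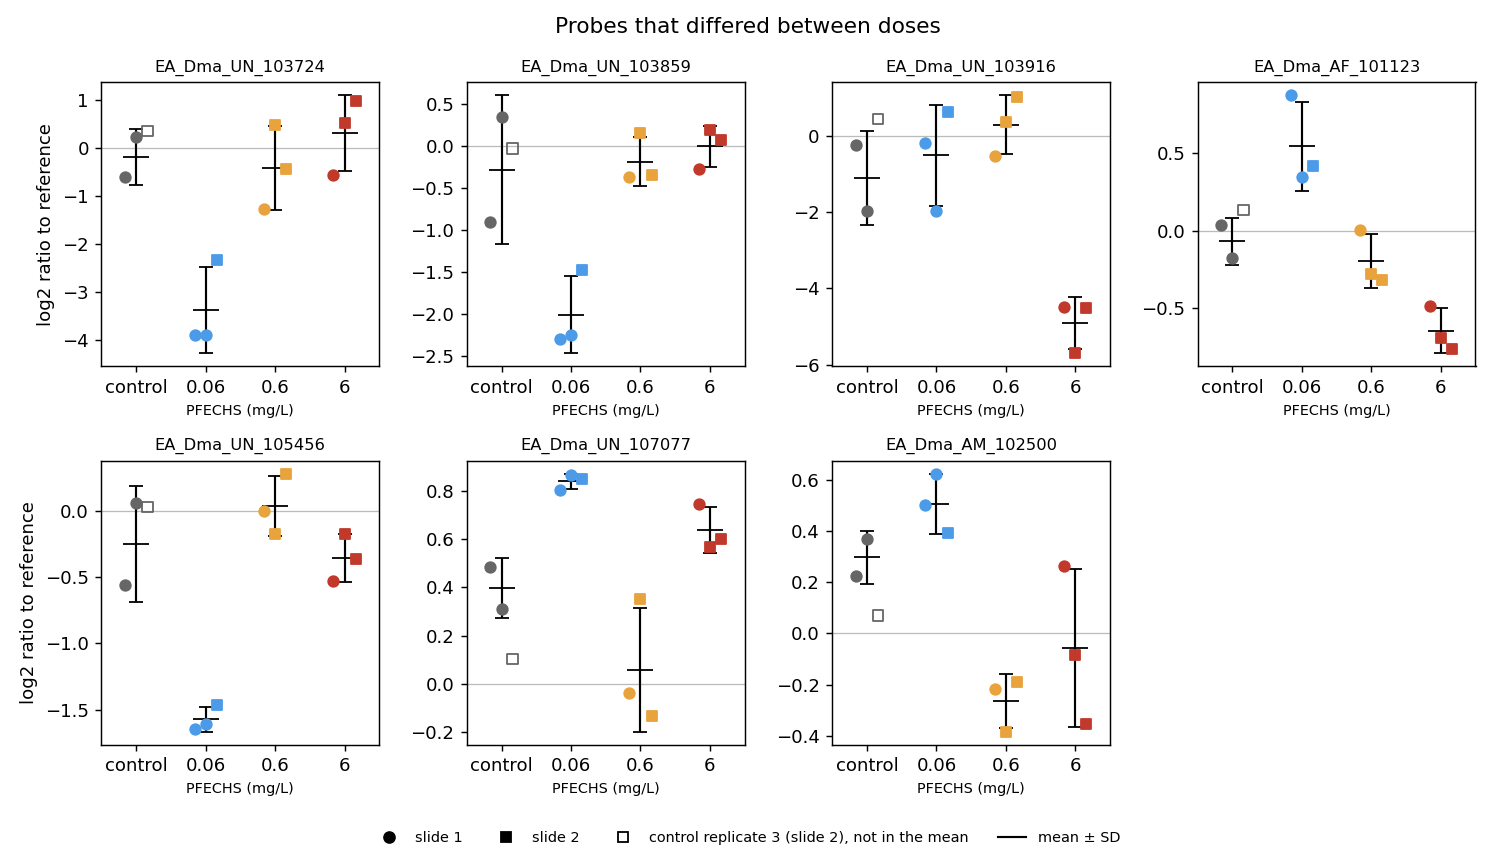
Log2 ratio of sample to reference (vertical axis) on each array, by PFECHS dose in mg/L (horizontal axis), for the 7 probes named in the comparisons between doses. Circles are slide 1, squares slide 2, the hollow square control replicate 3, and bars the mean ± SD without it. EA_Dma_UN_105456 lies between -1.64 and -1.47 on the 3 arrays at 0.06 mg/L and at or above -0.56 on the others.

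Between 6 and 0.6 mg/L, 0 of 7370 probes passed in limma and 588 had an unadjusted p under 0.05, 302 higher and 286 lower. The deposited table of the authors likewise had 0 Daphnia probes past the threshold here, with 729 unadjusted. With slide as a block and within slide 1 the count was 0, and within slide 2 it was 1. It was 27 without 0.6 mg/L replicate 2 and 2 without 0.06 mg/L replicate 2. For a slope over the 4 ascending dose ranks, 0 probes passed and 530 had an unadjusted p under 0.05, of which 148 were in the largest sequence family. The slope also passed for 0 probes with slide as a block and within slide 1, for 1 within slide 2, and for 5 with control replicate 3 included under array quality weights.

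The largest sequence family had a lower median in exposed animals than in controls, through its commonest sequence, others of like GC content and some richer in GC. Over its 368 probes that were well above background on all 12 arrays, the median log2 ratio was 0.92 and 0.41 on control replicates 1 and 2, and it lay between -0.04 and 0.36 on the 9 exposed arrays (mean 0.15 ± 0.12, SD). The mean of controls 1 and 2 was 0.52 above the exposed mean (exact two-sided permutation p = 0.0182 over 55 splits, Benjamini-Hochberg adjusted 0.0242 over 4 families), and 9 of 9 exposed arrays lay below both controls. Both controls lay on slide 1, and the 55 splits exchange arrays across slides. Within slide 1 there are 15 splits, so that the exact p of 0.0667 there was the smallest possible and the call did not pass. Of 21 other settings, 17 had enough splits to pass, and the call was kept in 16 of these. Mean differences were uneven within the family, with a median of 0.72 over the 160 copies of the commonest sequence. They were 0.25 over 113 probes of other sequences within 1 base of the family's median GC content and 0.10 over the 95 probes richer in GC. Of the 113 probes, 93 were copies of 1 dim sequence (median log2 intensity 6.96). Counted once per sequence, the 15 sequences of that group had a median of 0.48 (0.14 to 0.80), and the 79 richer in GC had 0.12 (-0.13 to 0.81). Group means were 0.20 ± 0.14, 0.06 ± 0.13 and 0.19 ± 0.08 (SD, n = 3 each) at 0.06, 0.6 and 6 mg/L. The difference was 0.50 within slide 1 and 1.71 within slide 2, whose lone control was replicate 3. It was 0.26 without control replicate 1 and 0.77 without control replicate 2, designs in which 1 control remained and the smallest possible p was 0.1, so that the exact test could not pass. With median centring it was 0.53 and did not pass. In the next 3 families by size the same difference was 0.13, 0.21 and 0.10. Their exact permutation p was 0.0182, 0.0364 and 0.0182 (Benjamini-Hochberg adjusted 0.0242, 0.0364 and 0.0242). The call was therefore not particular to the largest family, and 0.0182 is the smallest p that 55 splits allow. With the Cy5 channel alone it turned to -0.02 in the second family and -0.06 in the fourth, and it was 0.02 in the third, whose lowest control lay 0.61 below the highest exposed array.

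**Figure D3:**
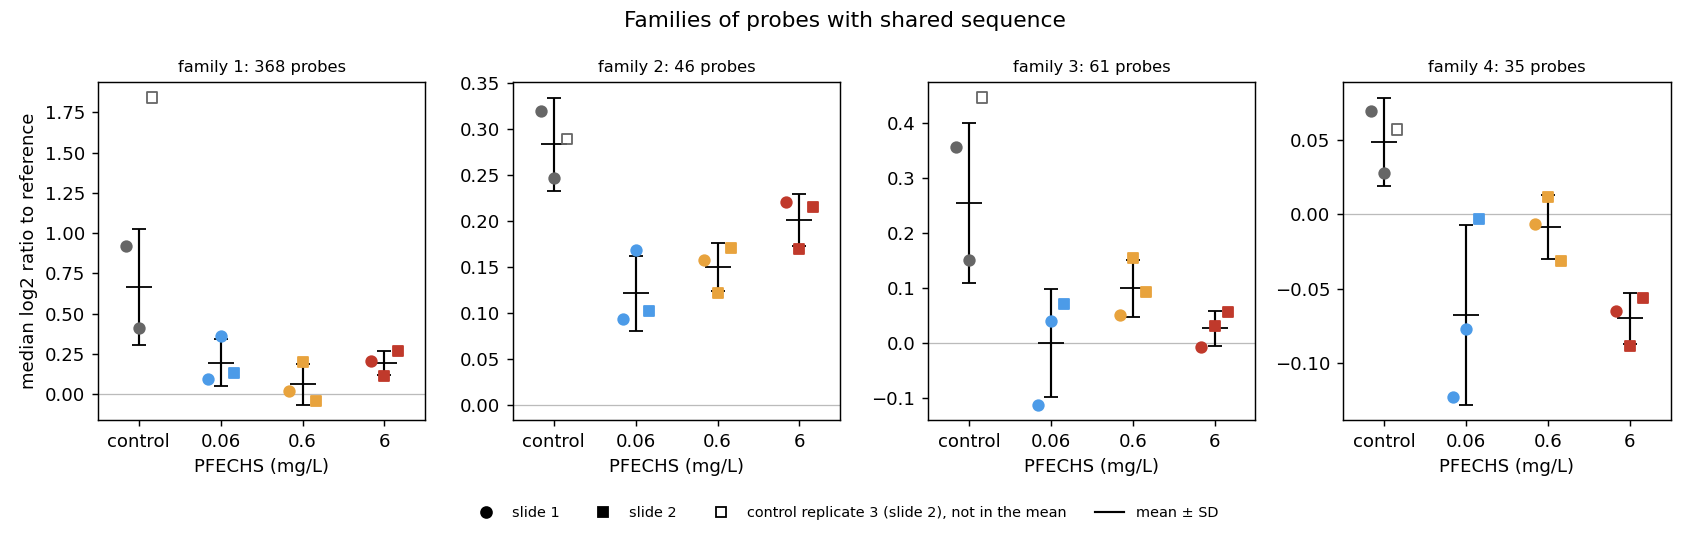
Median log2 ratio of sample to reference (vertical axis) on each array, by PFECHS dose in mg/L (horizontal axis), over the probes of each of the 4 largest sequence families that were well above background on all arrays. Circles are slide 1, squares slide 2, the hollow square control replicate 3, and bars the mean ± SD without it. In family 1 the 9 exposed arrays lie between -0.04 and 0.36 and controls 1 and 2 at 0.92 and 0.41, and in the Cy5 channel alone families 2 and 4 change direction and family 3 stands at 0.02.

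A few sets of probes varied together across arrays. Among 99 probes with an SD above 0.9 over the 12 arrays, 3 sets of 10 or more co-varying probes were found, a grouping chosen after the data were seen. Set 1 held 39 probes, among them EA_Dma_AF_102134 and EA_Dma_UN_107138, and its median log2 ratio was 2.23 on 0.06 mg/L replicate 3, 3.40 on 0.6 mg/L replicate 2 and 0.71 on 0.6 mg/L replicate 3, with the other arrays between -0.50 and 0.39. Set 2 held 24 probes, among them EA_Dma_UN_104730, EA_Dma_UN_104131, EA_Dma_UN_103724 and EA_Dma_UN_103859, with medians of -3.07, -3.17 and -0.94 on 0.06 mg/L replicates 1, 2 and 3 and between -0.52 and 0.67 elsewhere. Set 3 held 16 probes, EA_Dma_UN_103916 among them. Its medians were -1.59, -2.28 and -1.72 at 6 mg/L, -0.85 and -1.5 on control replicates 1 and 2, and 1.34, 1.28 and 1.14 on replicate 3 of the controls, of 0.06 mg/L and of 0.6 mg/L. The remaining arrays stood at -0.78 and -1.28 on 0.06 mg/L replicates 1 and 2 and -0.90 and -0.39 on 0.6 mg/L replicates 1 and 2.

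**Figure D4:**
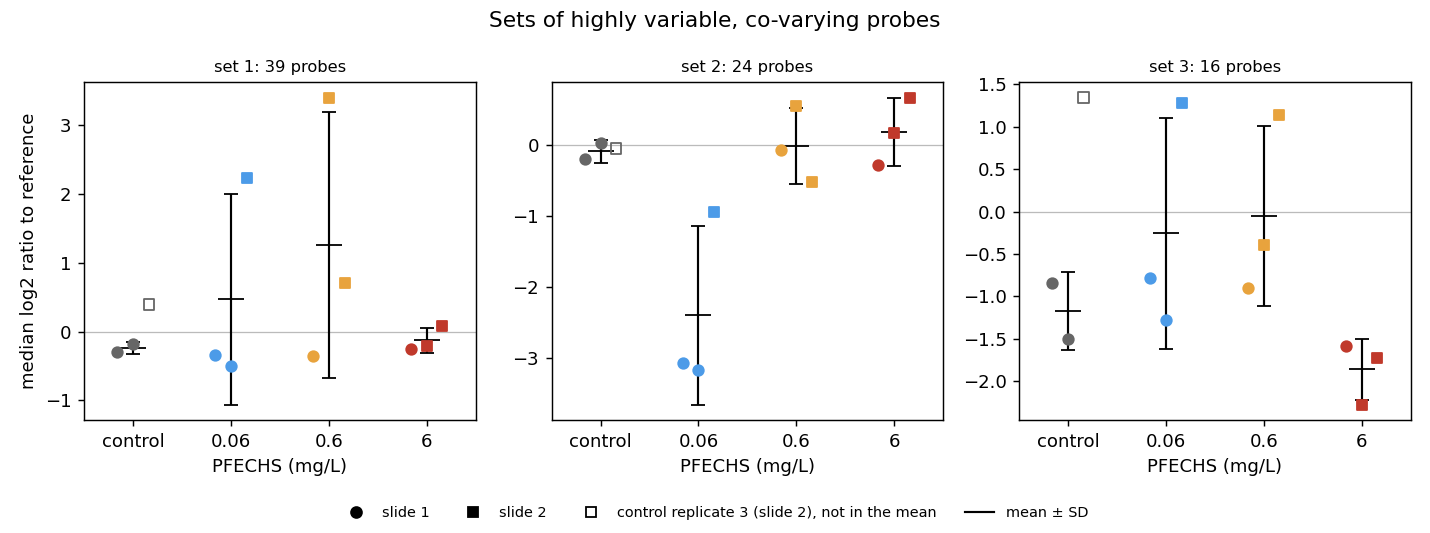
Median log2 ratio of sample to reference (vertical axis) on each array, by PFECHS dose in mg/L (horizontal axis), for 3 sets of co-varying probes. Circles are slide 1, squares slide 2, the hollow square control replicate 3, and bars the mean ± SD without it. Set 1 reaches 2.23 and 3.40 on 1 array each at 0.06 and 0.6 mg/L, and set 2 lies at -3.07 and -3.17 on 2 arrays at 0.06 mg/L.

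Fold changes against control were compared across probes between doses, as a description without a test, since probes are not independent replicates. Pearson's r was 0.52 between 0.06 and 0.6 mg/L, 0.42 between 0.06 and 6 mg/L and 0.47 between 0.6 and 6 mg/L. With 1 probe per sequence family these were 0.42, 0.30 and 0.28. Unchanged groups simulated against 2 shared controls gave a mean r of 0.60 for each pair. The covariances were 0.0424, 0.0284 and 0.0270, against 0.0207, 0.0207 and 0.0208 in the simulations, whose highest values were 0.0284, 0.0280 and 0.0275. With 2 controls, the controls could not be split into parts of 2 arrays. Each observed r lay below the simulated mean, so r by itself does not tell a common response from the shared controls. The covariance lay above the simulated highest for 0.06 with 0.6 mg/L, barely so for 0.06 with 6 mg/L, and below it for 0.6 with 6 mg/L. Part of each covariance may come from the shared controls. Slide may add to it as well, since both controls lay on slide 1 and each dose had arrays on slide 2, which was not tested. For 0.06 with 0.6 mg/L, r was 0.25 without 0.06 mg/L replicate 3 and 0.64 without control replicate 2. Blocked on slide, r was 0.58, 0.43 and 0.39 for the 3 pairs. Within slide 1 the values were 0.19, 0.53 and 0.27, and within slide 2, against control replicate 3 alone, they were 0.90, 0.72 and 0.81.

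The 19 gene lists fixed before the data were examined, among them yolk proteins, cuticle, globins and detoxification enzymes, matched 0 Daphnia probes by name, so that no list was tested at any dose.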

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

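The slide test, the background and normalization test and the narrow match on GC content of the largest sequence family were chosen after the result was seen. Control replicate 3, left out of the reported comparisons, stood apart in the largest sequence family, with a median log2 ratio of 1.84 against 0.92 and 0.41 on controls 1 and 2. In the third family it was the highest of the 3 controls without standing apart, at 0.446 against 0.36 and 0.15. In all, 284 probes on this array were over 2-fold from the mean of controls 1 and 2, of which 257 were higher and 217 belonged to the largest family, while 84 probes differed by as much between controls 1 and 2.

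The largest family was lower on the 9 exposed arrays than on controls 1 and 2. A slide difference would leave no gap within slide 1, where the controls lay 0.49604 above the 4 exposed arrays (SD 0.148), though the lower control was 0.05 above the highest of them and 15 splits are too few for the exact test to pass there. Background correction or normalization as the cause would shrink the gap by more than 50% in at least 1 of 4 other settings, and the smallest value was 0.49663. Base composition would move other probes as poor in GC, but outside the families only 2 probes of like intensity were (median difference 0.14604), too few to decide. Family 3, of like GC content but brighter, differed by 0.21. Its 61 sequences reached at most 0.38, against 0.72 over the commonest sequence of the largest family. They are linked by shared stretches and were brighter (median log2 intensity 12.31 against 10.60), so they cannot decide on base composition. It stays open as the whole or a part of the gap. Probes of the largest family richer in GC differed by a median of 0.10, with single sequences from -0.13 to 0.81. An effect of exposure may remain beside base composition, untested, but the 3 controls differed from each other by more than the exposed arrays did. The mean linear ratio was 1.11 in the exposed arrays and 2.27 over the 3 controls, raised by the left-out control replicate 3 (median log2 ratio 1.84). Such a ratio in the controls, although the reference is labelled as pooled controls, stays unexplained.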

How the results depend on the processing

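Edwards background correction, 1 probe per sequence family, the Arabidopsis probes kept and the outlier spots kept were chosen after the data were seen, and causes were not tested except where a setting's construction shows them. Replicate numbers showed no clear pairing of the 11 arrays without control replicate 3. Of 15 same-number pairs, 6 correlated above 0.1 (-0.488 to 0.383), and 3 of 11 arrays correlated best with their own number. This does not exclude pairing in single sets of probes. Set 3 was high on replicate 3 of the controls, of 0.06 mg/L and of 0.6 mg/L (1.34, 1.28 and 1.14), but not of 6 mg/L (-1.72). With the replicate block the counts were 0 for each dose against control, for the slope and for 6 against 0.6 mg/L, 35 for 6 against 0.06 mg/L and 19 for 0.6 against 0.06 mg/L. Signal over background limits dim probes.

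Counts are given in the order 6, 0.6 and 0.06 mg/L against control, slope, 6 against 0.06, 6 against 0.6 and 0.6 against 0.06 mg/L, where the reported ones are 0, 0, 0, 0, 26, 0 and 44. Control replicate 3 included gave 5, 1, 190, 0, 35, 0 and 47, with array weights 15, 1, 127, 5, 107, 0 and 60, and with slide as a block 0, 0, 254, 0, 17, 0 and 2. The highest weight, 2.46, fell on 6 mg/L replicate 1, where the background model left a high Cy5 median, and the next was 1.47. Each slide alone had groups with 1 array, and calls for these rest on the spread of the other groups. Slide as a block gave 0, 0, 2, 0, 16, 0 and 2, slide 1 alone 0, 0, 48, 0, 24, 0 and 38, and slide 2 alone, with fewer arrays and 1 control, 441, 388, 389, 1, 2, 1 and 0. No background correction gave 0, 0, 1, 0, 16, 0 and 12, Edwards 0, 0, 1, 0, 24, 0 and 18, scanner processed signals 0, 0, 0, 0, 1, 0 and 0, median centring 0, 0, 0, 0, 0, 1 and 0, and Cy5 alone 0, 0, 0, 1, 11, 0 and 5. The trended and robust model gave 0, 0, 18, 0, 30, 0 and 98. Only the 2 groups compared gave 6 for 6 against 0.06 mg/L and 2 for 0.6 against 0.06 mg/L, and the authors' deposited table gave 36 and 17. An adjusted p under 0.1 gave 0, 163, 114, 0, 70, 0 and 249, and an unadjusted p under 0.05 with a 1.5-fold change 202, 196, 337, 4, 170, 37 and 198. The dim filter, Aquantile (which leaves ratios unchanged), 1 probe per family and the Arabidopsis probes or outlier spots kept stayed within 1.5 times.

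Leaving out 1 array gave 0 to 241, 0 to 277, 0 to 316, 0 to 0, 1 to 84, 0 to 27 and 0 to 162. The highest came without control replicate 2 for the 3 doses (241, 277 and 316), without 0.06 mg/L replicate 3 for 84 and 162, and without 0.6 mg/L replicate 2 for 27. Calls higher against lower were 11 and 15 between 6 and 0.06 mg/L and 6 and 5 with Cy5 alone, and 28 and 16 between 0.6 and 0.06 mg/L against 9 and 3 without background correction, 14 and 4 with Edwards and 4 and 1 with Cy5 alone.

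Correlations are in the order 0.06 with 0.6, 0.06 with 6 and 0.6 with 6 mg/L. They were 0.647, 0.612 and 0.652 with control replicate 3 included, 0.704, 0.613 and 0.685 with slide as a block too, 0.188, 0.533 and 0.272 in slide 1, and 0.902, 0.724 and 0.813 in slide 2. With array weights the latter pair were 0.568 and 0.585, with 1 probe per family 0.296 and 0.280, and median centring gave 0.203 for 0.06 with 6 mg/L. Leaving out 1 array gave 0.254 to 0.644, 0.298 to 0.559 and 0.321 to 0.674. The 0.254 came without 0.06 mg/L replicate 3, and the 3 highest values without control replicate 2.

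EA_Dma_UN_106596 at 0.6 mg/L turned to 0.27 with control replicate 3 and slide as a block and to 1.81 in slide 2, and EA_Dma_UN_104131 at 0.06 mg/L to 0.61 in slide 2. Exposed minus control turned to 0.0217 in sequence family 2 and 0.0566 in family 4 with Cy5 alone. No other named probe turned in the settings run, with 145 losses and 17 gains of a call over all named probes and families.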

Other observations

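The slide test of the first set of co-varying probes and the simulated lists and counts were chosen after the result was seen, and the counts of the real splits and of the slide block were known before the other splits and the within-slide folds were computed. The 3 comparisons between doses each allow 10 splits of 6 arrays into 3 and 3, too few for a share under 0.05. Between 6 and 0.06 mg/L the real split gave 26 probes and the highest other split 0, so that 1 of 10 splits gave as many, and simulated arrays with correlated noise and no dose effect gave 26 or more in 3 of 100 simulations, or 0 of 100 with the fitted slide differences added. Between 6 and 0.6 mg/L the real split gave 0, as did the highest other, so that 10 of 10 gave as many.

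Between 0.6 and 0.06 mg/L the real split gave 44 probes, 1 of 10 splits gave as many, and the highest other split, which followed the slides, gave 21. The smaller of the within-slide median folds of the called probes was 0.49873 on the log2 scale, but these probes were chosen on the same arrays, and lists as long from simulated arrays with slide differences and no dose effect kept their direction within both slides for 100% of probes. With slide as a block 2 probes passed, and the median fold of the called probes was 0.57 (median SE 0.0946) against 0.60 (median SE 0.0929) as reported. Simulated arrays with the fitted slide differences and no dose effect passed 0.04 probes on average, or 0.12 and at most 10 when the noise kept the correlation between probes. Such noise alone passed 2.99 on average and gave 44 or more in 2 of 100 simulations. The mean was thus lower with slide differences added, which widen the residual spread of a fit without a slide term. These counts therefore cannot decide whether slide made the calls. Why most calls ended with slide as a block was not tested. EA_Dma_UN_105456 passed there (1.56, against 1.61 as reported), and slide stays open for the other called probes, though a lost call alone does not point to slide. EA_Dma_UN_107077 stood at -0.78 in both fits, while EA_Dma_UN_103859 moved from 1.82 to 1.66 and EA_Dma_AM_102500 from -0.77 to -0.69.

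The first set of 39 co-varying probes was high on 0.06 mg/L replicate 3 (2.23) and 0.6 mg/L replicate 2 (3.40), both on slide 2. A slide difference would raise the other 4 arrays of slide 2, of which the highest set median stood at 0.70608. EA_Dma_AF_102134 and EA_Dma_UN_107138 stood at 1.73 and 1.58 on control replicate 3 and at 2.90 and 2.04 on 0.6 mg/L replicate 3. They were low on 6 mg/L replicates 2 and 3, also on slide 2 (-2.03 and -1.20, and -3.78 and -3.53). The set median therefore does not settle slide for these 2 probes. A local defect would raise 1 of the 2 spots of a probe, and 89.744% of the probes had both spots above 1 on both arrays. A change in the reference channel would leave Cy5 flat, and the smaller rise in Cy5 alone was 2.8471. The doses do not separate these arrays from their replicates, and no biological explanation was tested.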
